A study of Mus musculus with 9 samples.

How the data were processed

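DNA methylation was measured by reduced representation bisulfite sequencing, in which genomic DNA is cut with MspI at CCGG sites, size-selected fragments are treated with bisulfite so that unmethylated cytosines read as thymines, and the amplified libraries are sequenced. The 9 mouse libraries came from cultured tail-tip fibroblasts of adult males (label TT, 5 libraries) and from embryos made by putting such fibroblast nuclei into enucleated C57/B6 oocytes (label NTZy14, 4 libraries). Each stage held the strain labels BDF1-CAST and X1. What the digits in NTZy14 stand for, and what cross or line X1 denotes, are not given in the sources used here.

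For each library the authors deposited a list of CpG positions with the count of calls seen and the count of methylated calls, as the deposited description of the files states. Positions are on mouse build mm9, per the submitters' processing notes. The aligner, the methylation caller and the handling of reads that match several places are not given in the sources used here. In each file the positions lie on the 19 autosomes and X, and the counts start at 1 call, so no coverage filter had been applied. The authors also deposited a table of methylation as a fraction from 0 to 1 for tiles of 100 bp. Of its columns, 7 belong to single samples analysed here. They served only as a check: recomputed from CpGs with at least 5 calls, at least 99.4% of the tiles in each column lay within 0.001 of the deposited fraction. A further column joins 2 libraries, and 18 columns belong to samples outside the set analysed here, so these 19 columns were not used. The CpG density of a tile is the authors' deposited value, the mean over its CpGs of the number of CpGs within 50 bp on either side.

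The deposited description says that the tag "a" marks a resequencing, so fibroblast libraries 1 and 1a were summed and counted as 1 sample. Across 1085568 CpGs with at least 10 calls in both, their levels correlated at r = 0.961, and the mean chi-square per CpG was 1.60, against 1.72 between libraries 1 and 2. This left 8 samples, 4 per stage and 2 per strain in each stage. BDF1-CAST samples bear the numbers 1 and 2 and X1 samples 3 and 4. BDF1-CAST libraries covered 1746590 to 1886972 CpGs and X1 libraries 1376884 to 1596888. Strain therefore cannot be told apart from such differences between libraries. No source says whether the samples came from separate animals or cultures, so each p-value measures the spread between these samples, which may be technical. Library depth ran from 25239364 to 41466097 calls over 1376884 to 1886972 CpGs, with medians of 8 to 19 calls per CpG. Reads carried no molecular identifiers in the sources used here, so counts of calls are not counts of molecules.

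The mean methylation of a sample was taken over CpGs with at least 10 calls in every library, each CpG weighted equally, and stages were compared by a two-sided exact permutation test over the 70 assignments of 4 against 4, for which the smallest possible p is 0.0286. Calls were summed in tiles of 100 bp that start at multiples of 100, as in the deposited table, and tiles with at least 10 calls in every sample were tested. Each tile was fitted with a quasi-binomial logistic model of methylated and unmethylated calls with stage and strain as terms. The dispersion was moderated across tiles with squeezeVar of limma 3.58.1 in R 4.3.3 and kept at 1 or above, and the F test was adjusted by Benjamini-Hochberg. A tile was called at an adjusted p under 0.05 and a difference of at least 20 percentage points between mean sample levels. The strain term was tested in the same model, and the product of stage and strain in a model with both, without a minimum difference. Change by starting level used the fibroblasts of 1 strain to place a tile in a class and the samples of the other strain to measure its change, in both directions. Other steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. These choices, and the alternatives in coverage, weighting, treatment of libraries 1 and 1a, chromosomes, pairing, left-out samples, minimum difference, covariates, model and tile size, were fixed before the data were examined. Methylated tiles, for the comparisons by CpG density and chromosome, are those at 60% or more in the fibroblast mean. Those comparisons, the joining of called tiles within 1000 bp into regions, and the analysis of CpG spacing were chosen after the data had been seen.

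The tile model was tested on simulated data, with the real call numbers of the 279699 tiles and a spread between samples estimated from them. The spread of a tile was averaged over the stages and used for every sample, and no strain effect was simulated. In the real data the median SD was 6.38 points in fibroblasts and 11.8 points in NT embryos, among tiles between 10 and 90%. The rates below therefore need not hold for the real calls. For the stage comparison, with 20000 methylated tiles lowered, the model called 76.0% of those lowered by 40 points and 19.1% of those lowered by 20 points, and 2.90% of its calls were unchanged tiles. With only 200 tiles lowered it called none of the 100 lowered by 40 points, although 95.0% of them had an unadjusted p under 0.05, so a small number of changed tiles could not be recovered among this many. Of the unchanged tiles, 6.22% had an unadjusted p under 0.05.

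The reference at hand was a table of 49997 mouse genes on a later assembly than the mm9 positions of the files. Coordinates were not carried between builds, so tiles are given by position, what gene or element lies there was not determined, and the promoter comparison and the 10 gene lists planned for it were not run. Start positions are as deposited, and whether the files count bases from 0 or from 1 is not given in the sources used here. The tiles named are the 8 largest falls and the 8 largest rises among tiles called between the stages that moved the same way in each of the 4 pairs of samples with the same number, and for the strains the 4 largest called differences in each direction, by a rule fixed in advance.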

Results

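Methylation of single CpGs was compared between adult tail-tip fibroblasts, which served as nuclear donors, and embryos reconstructed by transferring such nuclei into enucleated oocytes, here called NT embryos (label NTZy14). The comparison addresses how far the methylation of a somatic nucleus has changed in the egg. Each stage held 4 samples, 2 labelled BDF1-CAST and 2 labelled X1. The fibroblast libraries held 35442175 to 41466097 calls and the NT embryo libraries 25239364 to 30396273. Over the tested tiles, the median number of calls per tile ranged from 59 to 131 among fibroblast samples and from 38 to 47 among NT embryo samples, so levels in NT embryos were the less precise ones. Among tiles between 10 and 90%, the median SD between samples was 6.38 points in fibroblasts and 11.8 points in NT embryos.

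Methylation was lower in NT embryos than in fibroblasts. Over 432895 CpGs, of which 14317 lie on X, the mean level was 33.3% ± 0.804 (SD, n = 4) in fibroblasts and 29.8% ± 1.78 (SD, n = 4) in NT embryos. The difference of -3.51 points reached the smallest p the design allows (two-sided exact permutation test, p = 0.0286), and each NT embryo sample lay below each fibroblast sample. The shift was one from full to intermediate methylation. CpGs at 80% or more made up 25.96% ± 2.01 of those measured in fibroblasts and 17.9% ± 4.49 in NT embryos, while CpGs between 20 and 80% rose from 15.5% ± 1.47 to 21.9% ± 3.89 (exact permutation p = 0.0286 for each, n = 4 per stage). CpGs under 20% made up 58.6% ± 0.585 and 60.2% ± 0.822, a difference that did not pass the test (exact permutation p = 0.0571). The mean changed by -4.38 points in BDF1-CAST samples and by -2.63 points in X1 samples. With CpGs weighted by their calls, the difference was -5.43 points and the exact permutation p was 0.0571. Without any 1 of the fibroblast samples the p was also 0.0571.

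**Figure D1:**
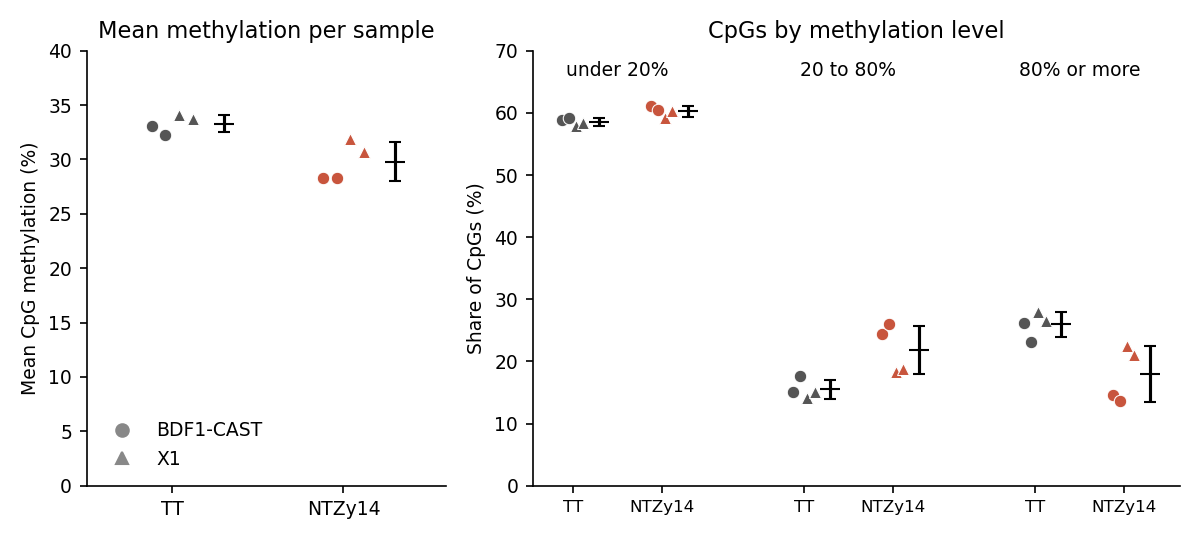
Left, mean CpG methylation in percent of each of the 4 fibroblast (TT) and 4 NT embryo (NTZy14) samples; right, share of CpGs in percent at 3 levels of methylation. Points are samples, circles BDF1-CAST and triangles X1, and bars give mean and SD; the highest NT embryo mean is 31.9% and the lowest fibroblast mean 32.3%.

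Sequence that was highly methylated in fibroblasts lost methylation to different degrees from place to place, and unmethylated sequence stayed unmethylated. Of 109675 tiles of 100 bp at 80% or more in fibroblasts, 36.4% were still at 80% or more in NT embryos, 52.6% lay at 60 to 80%, 10.6% at 20 to 60% and 0.339% under 20%. Of 102729 tiles under 20% in fibroblasts, 97.0% stayed under 20%, and 52 tiles reached 60% or more. Of 279699 tiles tested, 12826 were called, 12341 of them lower in NT embryos and 485 higher (quasi-binomial model with limma-moderated dispersion, adjusted p under 0.05 and at least 20 points). All 4 same-numbered pairs of samples moved the same way in 12056 of the called tiles. Among tiles called lower, the median level was 85.3% in fibroblasts and 40.3% in NT embryos, and the median of the changes was -38.5 points. Falls of 60 points or more were seen in 1124 called tiles, and 353 went from at least 80% to under 20%. The count depended on the samples: it was 0 without fibroblast sample 1, 1448 without sample 2, 3307 without sample 3 and 3464 without sample 4, and 7099 and 6989 without NT embryo samples 1 and 2. At 20 calls per tile 5750 tiles were called, and limma on arcsine square root levels called 7076. Single CpGs gave 0 calls, with 60361 at an unadjusted p under 0.05.

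The 8 largest falls were near-complete losses, from 91.6 to 98.3% in fibroblasts to between 1.72 and 9.11% in NT embryos (build mm9). The largest was on chromosome 19 at 5287100 to 5287199, a tile of 8 CpGs that fell from 95.0% ± 4.45 to 2.87% ± 5.74 (SD, n = 4, adjusted p = 0.00625, 18 to 265 calls per sample). On chromosome 16, tile 23165100 to 23165199, with 4 CpGs, fell from 93.8% ± 4.93 to 3.13% ± 4.29 (adjusted p = 0.00527), with as few as 11 calls in a sample. On chromosome 11, tile 120782000 to 120782099, with 4 CpGs, fell from 94.4% ± 2.64 to 4.08% ± 8.15 (adjusted p = 0.00420, 36 to 300 calls). On chromosome 7, tile 52301400 to 52301499, with 5 CpGs, fell from 91.6% ± 3.46 to 1.72% ± 2.24 (adjusted p = 0.00275, 23 to 348 calls). The other 4 were on chromosome 2 at 153411200, on chromosome 7 at 54107100, on chromosome 8 at 83370800 and on chromosome 16 at 92427600, with changes of -90.1, -89.2, -89.2 and -88.4 points. These 4 tiles held 1, 2, 3 and 2 CpGs.

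Rises were fewer and smaller. Among tiles called higher, the median level was 25.6% in fibroblasts and 64.3% in NT embryos, and the median of the rises was 32.3 points. The largest was on X at 48321600 to 48321699, where methylation rose from 24.8% ± 12.1 to 100% in each of the 4 NT embryo samples (adjusted p = 0.00504, 12 to 63 calls). On chromosome 15, tile 27927400 to 27927499 rose from 16.3% ± 15.8 to 79.8% ± 13.0 (adjusted p = 0.00629), and on chromosome 10, tile 118920700 to 118920799 rose from 27.0% ± 14.1 to 82.8% ± 7.54 (adjusted p = 0.00660). The other 5 rose by 56.1 to 62.0 points, on chromosome 17 at 30873200, chromosome 15 at 5761500, chromosome 9 at 59887000 and 114921500, and chromosome 8 at 120713300. Each of the 8 named rises was a tile of only 1 or 2 CpGs. Without fibroblast sample 1 none of the 16 named tiles that fell or rose was called (adjusted p from 0.0666 to 0.163). Tile 92427600 on chromosome 16 was also not called without fibroblast sample 2 (adjusted p = 0.0539), and the rise at 120713300 on chromosome 8 without any 1 of the fibroblast samples. The rises at 30873200 on chromosome 17, 5761500 on chromosome 15 and 59887000 on chromosome 9 were not called without any 1 of the fibroblast samples or without NT embryo sample 1 or 2, and the last also not without NT embryo sample 3 (adjusted p = 0.0537). Limma on arcsine square root levels did not call those at 5761500 and 59887000 (adjusted p = 0.0530 and 0.0702). Fibroblast levels at these rises were themselves variable, with SDs from 4.41 to 16.5 points among the 8 tiles.

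Most called tiles stood alone. Joined within 1000 bp, the tiles called lower formed 10853 regions, of which 88.8% held 1 called tile and 204 held 3 or more. The longest run, 7 tiles on chromosome 16 between 17803100 and 17804699, fell from 45.1% ± 9.95 to 7.28% ± 5.52. A region of 6 tiles on chromosome 10 between 67559700 and 67560599 fell from 92.9% ± 2.57 to 45.4% ± 10.7, and 1 of 6 tiles on chromosome 8 between 90184200 and 90185599 fell from 59.3% ± 3.40 to 17.0% ± 5.47. The tiles called higher formed 459 regions, 3 of them with 3 or more tiles. The longest, 4 tiles on chromosome 4 between 134953300 and 134953999, rose from 18.7% ± 6.14 to 52.1% ± 12.9, and 3 tiles on chromosome 9 between 21935900 and 21936499 rose from 5.54% ± 0.398 to 46.5% ± 11.7.

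Over all tiles, the 3 classes at 40% or more in fibroblasts lost methylation. With the class of a tile taken from the fibroblasts of the other strain, tiles at 80 to 100% changed by -11.3 points ± 2.87 (SD, n = 4 NT embryo samples), tiles at 60 to 80% by -11.0 ± 2.25 and tiles at 40 to 60% by -9.38 ± 2.56. Each of the 4 samples was lower in these 3 classes. Tiles at 20 to 40% changed by -3.01 ± 3.28, with 3 of 4 samples lower, and tiles at 0 to 20% by 0.329 ± 0.573, which is within the spread between samples. These changes carry no test of their own.

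**Figure D2:**
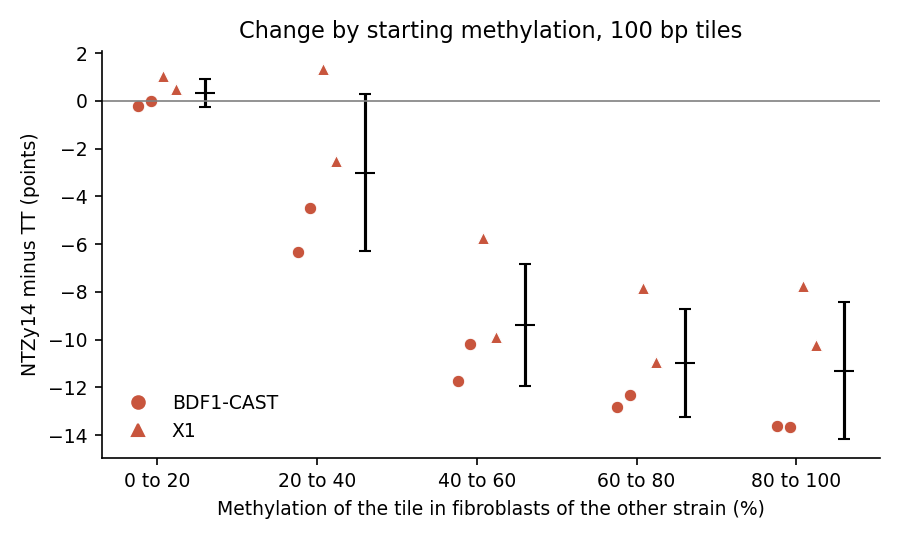
Change in methylation, NT embryo (NTZy14) minus fibroblast (TT), in percentage points, against the tile's methylation in percent in fibroblasts of the other strain. Points are the 4 NT embryo samples, circles BDF1-CAST and triangles X1, and bars give mean and SD; tiles at 80 to 100% lie between -13.7 and -7.74 points and tiles at 0 to 20% between -0.220 and 1.06.

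The loss was seen at each CpG density, with the highest share of called tiles, among classes of over 1000 tiles, at a density of 3 to 4 CpGs. Methylated tiles of that density went from 81.7% ± 2.14 to 66.8% ± 4.65 (exact permutation p = 0.0286, n = 4 per stage), and 12.3% of them were called lower. At a density of 1 to 2 the change was -10.9 points with 3.99% called, and at 6 to 8 it was -9.34 points with 6.39% called (exact permutation p = 0.0286 for each, the same for the 7 density classes examined).

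The X chromosome lost less than the autosomes. Methylated tiles on X went from 83.6% to 76.5%, a change of -7.10 points, against -9.56 to -17.1 points on the 19 autosomes. Chromosome 11 changed the most, with 13.4% of its 6359 methylated tiles called lower, and chromosome 19 followed with 12.4%, while 1.72% of the 11489 methylated tiles on X were called lower. In fibroblasts methylated tiles on X lay 0.712 points ± 0.152 above those on autosomes, and in NT embryos 5.40 points ± 0.553 above them (exact permutation p = 0.0286, n = 4 per stage). With autosomal tiles reweighted to the density and starting level of those on X, the change of X minus that of the autosomes was 4.56 points (exact permutation p = 0.0286). In methylated windows of 5 CpGs matched in the same way it was 3.06 points, and with the number of occurrences of the CpG spacing matched as well it was 1.18 points (exact permutation p = 0.0286 for each).

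**Figure D3:**
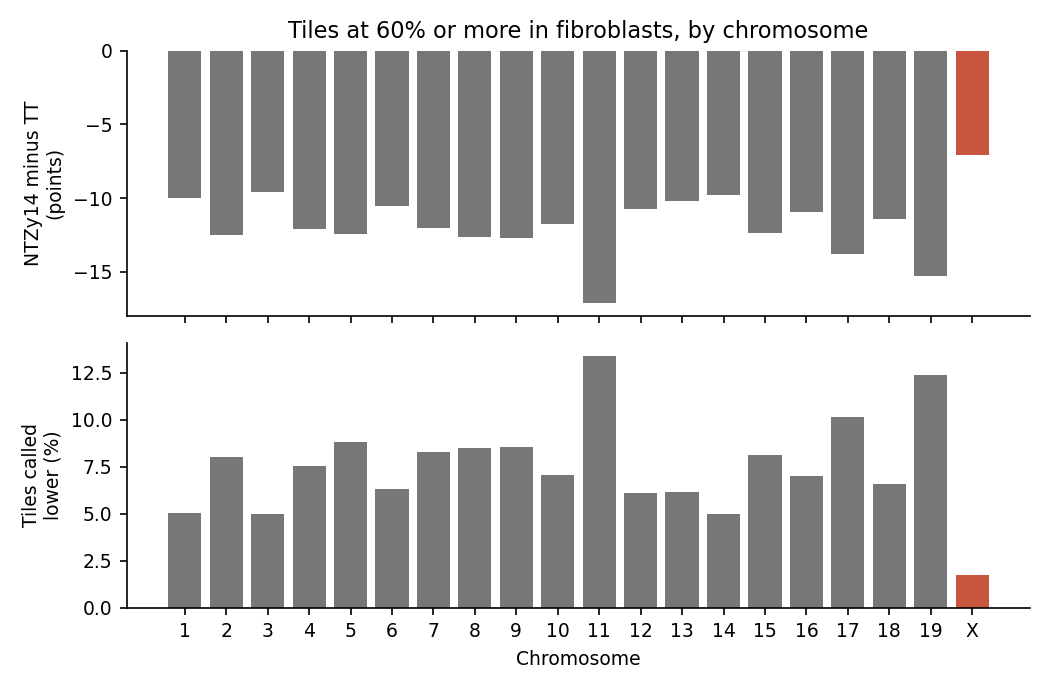
Tiles at 60% or more in fibroblasts, by chromosome: above, mean change in percentage points (NT embryo minus fibroblast); below, share of these tiles called lower in percent. Bars are single values per chromosome over all samples, with X in red at -7.10 points and 1.72%, outside the range of the autosomes.

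In the quasi-binomial model with limma-moderated dispersion, 50 tiles were called between the strains BDF1-CAST and X1, while 44237 of the 279699 tiles had an unadjusted p under 0.05. Of the 50, 30 were higher and 20 lower in X1, and 6 were also called between the stages. Strain cannot be told apart here from the difference in covered CpGs between the libraries of the strains. The largest difference was near all-or-none in both stages. Whether sequence variants remove CpGs from the tiles named below was not examined. On chromosome 3, tile 123375000 to 123375099 was at 96.1% ± 3.64 in BDF1-CAST and 0% in each of the 4 X1 samples (adjusted p = 0.00646, 27 to 126 calls per sample). On chromosome 4, tile 135778800 to 135778899 was at 80.9% ± 6.95 in BDF1-CAST and 0% in each X1 sample (adjusted p = 0.0115), as was tile 125283800 on chromosome 5 at 70.6% ± 9.01 against 0% (adjusted p = 0.0281). On chromosome 4, tile 128767000 was at 75.7% ± 18.1 against 12.02% ± 13.9. In the other direction, adjoining tiles on chromosome 1 at 172975200 and 172975300 were at 3.72% ± 4.06 and 0.463% ± 0.926 in BDF1-CAST and at 78.4% ± 7.06 and 80.5% ± 15.5 in X1. On chromosome 5, tile 31637700 was at 17.6% ± 16.9 against 94.2% ± 9.13, and on chromosome 7, tile 105989900 was at 27.8% ± 15.1 against 93.7% ± 4.46. The named strain tiles held from 1 CpG (at 105989900) to 4 CpGs (at 31637700). None of these 8 tiles was called without any 1 of the fibroblast samples (adjusted p from 0.109 to 0.296) or without NT embryo sample 1 or 2 (0.0528 to 0.159), and without NT embryo sample 4 they missed as well (0.0507 to 0.126). Without NT embryo sample 3 only those at 123375000 and 135778800 were called. The tiles at 31637700 and 105989900 were also not called without library 1a (adjusted p = 0.0596 and 0.0736), with no covariate (0.143 and 0.105) or with limma (0.155 for each), those at 172975200 and 172975300 not with limma (0.116 and 0.131), and those at 128767000 and 172975300 not with no covariate (0.187 and 0.0513). The count was unstable: without 1 sample it lay between 0 and 12, limma on arcsine square root levels gave 8, and tiles of 1000 bp gave 412.

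No tile was called for a stage by strain interaction, that is, for a change between stages that differs between BDF1-CAST and X1. The quasi-binomial model with limma-moderated dispersion gave a smallest adjusted p of 0.253, and 24277 tiles, or 8.68% of those tested, had an unadjusted p under 0.05. Limma on arcsine square root levels also called 0 tiles, with 25202 at an unadjusted p under 0.05. Each stage and strain held only 2 samples, and no interaction was simulated to see what the model could find. The 0 therefore does not show that the strains changed alike. Whether the mean change of -4.38 points in BDF1-CAST differs from that of -2.63 points in X1 was not tested.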

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

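The tests of this part were chosen after the values had been seen. Of 78 groups of 4 or 5 values looked at, 5 held a sample set apart by a gap that was large against the range of the group. Chance at 1 in 20 gives 3.9, a rate that need not hold where the other samples are at or near 0%. In such a group even a small difference counts, as in the last of the 5. In tile 5287100 on chromosome 19, NT embryo sample 1 was at 11.5% and the other 3 at 0%. In tile 120782000 on chromosome 11, NT embryo sample 2 was at 16.3% and the other 3 at 0%. In tile 92427600 on chromosome 16, NT embryo sample 3 was at 20.9%, with the others between 0 and 1.56%. In tile 120713300 on chromosome 8, NT embryo sample 1 was at 50%, with the others between 84.4 and 88.5%. In the strain tile 172975300 on chromosome 1, fibroblast sample 2 was at 1.85% and the other BDF1-CAST samples at 0%.

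In 6 cases each NT embryo sample of BDF1-CAST lay below its strain's fibroblast mean and each NT embryo sample of X1 above it; the difference was not tested in any of them. Tiles at 0 to 20% changed by -0.120 points in BDF1-CAST and 0.779 points in X1, a difference of 0.899 points. The others are 5 of the 10 families of recurring CpG spacing described under the other observations. These 5 may not be distinct cases. Those below with a last gap of 24 bp repeat the gaps of the family of 7, 5, 4 and 29 bp, with neighbouring gaps joined. The family with gaps of 7, 5, 4 and 29 bp changed by -2.98 points in BDF1-CAST and 1.05 points in X1, a difference of 4.04 points, and that with gaps of 8, 2, 16 and 8 bp by -2.55 and 2.56 points, a difference of 5.11 points. The family with gaps of 7, 9, 29 and 24 bp changed by -1.92 and 2.30 points, a difference of 4.22 points, that with gaps of 7, 5, 33 and 24 bp by -1.99 and 2.14 points, a difference of 4.13 points, and that with gaps of 12, 4, 29 and 24 bp by -2.32 and 1.87 points, a difference of 4.19 points.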

How the results depend on the processing

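No difference changed direction in an alternative that gave a value, except that of tiles at 0 to 20%, which was -0.0284 points weighted by calls, within its spread. The global difference ran from -4.52 to -3.10 points when single samples were left out and was -5.43 weighted by calls (exact permutation p = 0.0571). The count of tiles called between the stages was 20068 at 5 calls, 5750 at 20 calls, 7076 with limma on arcsine square root levels and 23755 with tiles of 1000 bp, and ran from 0 to 16399 when single samples were left out. It was 0 for single CpGs, with 60361 at an unadjusted p under 0.05. At least 94.7% of the calls were lower in NT embryos wherever a setting called any. At 5 calls the set held each of the 12826 tiles, and limma kept 6617 of them.

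The strain count of 50, 20 lower and 30 higher in X1, moved both in size and in its split. It was 29 lower plus 72 higher at 20 calls, or 1.0e2 in all, 344 with libraries 1 and 1a as 2 samples (76 lower, 268 higher), 32 without 1a, 20 with no covariate (11 lower, 9 higher), 8 with limma (6 lower, 2 higher), 412 with tiles of 1000 bp (65 lower, 347 higher) and 0 for single CpGs (32701 at an unadjusted p under 0.05), and ran from 0 to 12 without single samples. The interaction count ran from 0 to 1, the 1 without NT embryo sample 4. The cause of these shifts was not tested. The change of tiles at 80 to 100%, that of the other classes, and the X to autosome difference moved by less than their spread or stayed past the test under each setting run; leaving out samples for these, and the settings for X and for CpGs at 80% or more, were added after seeing the data. CpGs at 80% or more passed the test except without 1 of the 4 fibroblast samples.

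The samples share numbers, but whether the numbers pair them is not settled. Deviations of same-numbered samples correlated at 0.111, 0.127, 0.196 and 0.0427. With the other NT embryo sample of the strain the fibroblast samples correlated at 0.129, 0.162, 0.152 and 0.0558. Only 1 of 4 fibroblast samples correlated best with its own number, but with so few samples that cannot show that pairing is absent. With the replicate block the difference of -3.51 points had an exact sign-flip p of 0.125, the smallest that 4 pairs allow, and the model called 0 tiles, with 56966 at an unadjusted p under 0.05. In simulated data the blocked model also called 0 of 10000 tiles lowered by 40 points, so its 0 says nothing about the change. Promoters and gene lists, with all their alternatives, were not run for lack of an annotation on mm9.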

Other observations

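The tests of CpG spacing, X chromosome, X coverage, conversion, rises and strain CpGs were chosen after the data had been seen; the counts of other splits were planned. Where no annotation is at hand, the spacing of neighbouring CpGs can show sequence that recurs in the genome. Windows of 5 CpGs with gaps of at most 60 bp were compared by their 4 gaps, read in either direction. Among windows at 60% or more in fibroblasts, the 12339 whose spacing occurs once went from 81.3% ± 2.31 to 61.9% ± 5.77 (SD, n = 4), a change of -19.4 points, and 44.1% of them fell by 20 points or more. Spacings found 2 to 9 times changed by -12.6 points, those found 10 to 99 times by -7.57 points and those found 100 times or more but under 1000 by -7.80 points (exact permutation p = 0.0286 for each). The 9 spacings found 1000 times or more changed by -6.23 points (exact permutation p = 0.114).

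Recurring spacings fell into 10 methylated families, which may not all be distinct, since some repeat the gaps of another with neighbouring gaps joined. Their mean changes ran from -15.4 to 0.191 points, and no family passed the test after adjustment over the 10. The family with gaps of 7, 5, 4 and 29 bp, at 3630 loci on all 20 chromosomes, was at 87.4% ± 1.08 in fibroblasts and 86.4% ± 3.26 in NT embryos, a difference that did not pass the test (exact permutation p = 0.60). The family with gaps of 8, 2, 16 and 8 bp, at 1294 loci, was at 88.0% ± 0.708 and 88.0% ± 2.74 (exact permutation p = 1.00). By contrast the family with gaps of 21, 12, 45 and 25 bp, at 2225 loci, went from 86.4% ± 1.85 to 71.0% ± 11.5, and that with gaps of 3, 7, 17 and 21 bp, at 1484 loci, from 88.6% ± 1.02 to 74.3% ± 11.2 (exact permutation p = 0.0286 for each, adjusted 0.0714 over the 10 families). These falls were uneven between the strains: the former was -23.8 points in BDF1-CAST and -7.05 in X1, the latter -23.1 and -5.40. That difference was not tested, and strain cannot be told apart from other differences between the libraries. What elements these are was not determined, and reads that match several copies may have been placed at any of them, so each value is that of the family more than of a locus.

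The first pattern is the fall itself. Of the 35 splits of the 8 samples into 4 and 4, only the 1 by stage called 11062 tiles or more with group alone in the model. The highest of the others called 20. A share of 1 in 35 is the smallest that these splits allow, and each other split mixes the stages. Chance is therefore an unlikely source of the fall but cannot be excluded. Poor retention of methylated calls in bisulfite conversion would lower all highly methylated sequence alike. By contrast, the least changed of the 10 families, picked for its small loss, lost -0.00562% of its level (spread 3.21). This family, with gaps of 8, 2, 16 and 8 bp, changed by -2.55 points in BDF1-CAST and 2.56 points in X1. Unique windows lost 23.9%, but each was chosen at 60% or more in these same fibroblasts, and the family by its mean. DNA of the egg or its polar body holds an X chromosome in each chromosome set and male donor DNA in 1 of 2. The X to autosome ratio of calls was 12.3% ± 9.06 higher in NT embryos, as such DNA would leave it (exact permutation p = 0.0286, each NT embryo sample above each fibroblast sample). Among tiles called lower, the median NT embryo level was 52.7% below the median fibroblast level. If the ratio follows X copy number, it would have to rise by at least 52.7% to give that fall, even with unmethylated egg DNA. Whether it does was not tested. Calls were capped at 200 per CpG, and the ratio was 0.752 in fibroblasts and 0.845 in NT embryos. The called tiles were also chosen for their fall, so 52.7% may be too large. The ratio therefore sets no firm bound on egg DNA in these tiles. Methylated tiles outside the calls lost 11.1%, which the rise in the ratio would allow. Admixed DNA that is evenly unmethylated would lower X more than the autosomes, and over all methylated tiles X lost 4.69 points less than the autosomes (exact permutation p = 0.0286). In the methylated tiles outside the calls, X lost 7.96% of its level and the autosomes 11.3%, a difference that was not tested. That order is the reverse of what evenly unmethylated DNA alone would give. The methylation of egg DNA was not measured, so for these tiles an admixture cannot be told apart from a change of the donor genome. Tiles that rose by 20 points or more in 1 strain lay above tiles of the same start in the other. The mean excess was 10.4 points (chosen in BDF1-CAST) and 4.43 points (chosen in X1). The same-start tiles changed by -2.35 and -5.97 points, so an excess can also come from a smaller loss. Tiles chosen in BDF1-CAST rose by 8.07 points in X1, with 62.4% in the same direction. Noise of the NT libraries is therefore unlikely to account for all of these rises. Tiles chosen in X1 changed by -1.54 points in BDF1-CAST, with 45.5% in the same direction. Their excess is no evidence of a rise beyond noise, and much of the rises may be noise.

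The second pattern is the part played by sequence class. The change of the family with gaps of 7, 5, 4 and 29 bp differed by 14.5 points from that with gaps of 21, 12, 45 and 25 bp (exact permutation p = 0.0286, adjusted 0.0545 over 21 contrasts), as multi-copy elements that keep or lose methylation by family would give, and by 13.9 to 14.4 points when averaged over windows at 5 or 20 calls or on autosomes alone. X lost 4.56 points less than autosomal sequence matched on density and level. Recurring sequence takes part in this gap: X held 3.64% of unique windows but 11.1% of those whose spacing occurs 100 times or more but under 1000 and 10.9% of those beyond. In windows the gap was 3.06 points matched on density and level and 1.18 points (spread 0.250) with occurrences matched too (exact permutation p = 0.0286 for each), so a larger share of recurring sequence on X is not the whole of it. The gap was 10.2 points in unique windows (exact permutation p = 0.0286). Within the 6 families with the most loci it lay between -0.707 and 0.318 points (exact permutation p from 0.429 to 0.914). If reads of copies on X and on autosomes were exchanged, which was not tested, a gap near 0 would be found in families in any case, so whether the gap differs between unique and recurring sequence stays open.

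The third pattern is the strains. By strain 20 tiles were called with group alone in the model, and 2 of the 35 splits called as many. The other was the split by stage with 11062, which reflects the stages, and the highest of the rest called 0. With the stage split among the 35, a share under 0.05 could not be reached. At single CpGs, 927 of 441105 differed by 40 points or more between the fibroblasts of the strains without overlap, against 38 and 18 when 1 sample of each strain was exchanged. In NT embryos 87.3% of them differed with the same sign, and the mean difference towards that sign was 33.0 points. Of them, 724 had an adjacent tested CpG within 50 bp, and 2 such neighbours were averaged. The neighbours showed 41.1% ± 2.72 (bootstrap SD) of the difference, 13.8 against 33.6 points. Variants that remove a CpG in 1 strain may thus account for part of them, while differences that extend to neighbours are left over. A neighbour could itself be among the 927. The bootstrap drew CpGs as if independent and left out the spread between samples, so its SD may be too small. Of the 681 CpGs higher in X1, 58.3% were at 30 to 60% in BDF1-CAST, a level that a CpG missing from 1 of 2 alleles would also give. The choice by a difference of 40 points or more already holds the lower strain at 60% or less, in either direction. That share therefore cannot tell whether an allele lacks the CpG. Of the 246 lower in X1, 21.1% were at 30 to 60% in X1 and 66.7% under 20%. A CpG missing from 1 of 2 alleles would not give so low a level, but one missing from both alleles could. Whether a variant lies at these CpGs was not examined.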
